A study of Mus musculus with 311 samples.

How the data were processed

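Liver total RNA of 311 F2 animals was measured on 2-color arrays, each against a common pool, and all arrays form 1 group called F2 liver. The deposited values are log10 ratios limited to -2 and 2, already normalized by the authors in a way not given in the sources used here. The labels name both dyes and the pool. The base and the sign of the ratio (sample over pool) were derived from the values: the slope of each gene's mean on its variance was compared with the slope a pool of all samples requires. The values were used as deposited, without further normalization. Array medians lay between -0.0218 and 0.0172 and array SDs between 0.0658 and 0.206. In total 0.745% of values were missing and 1990 lay at a limit. A total of 127 of 48205 pairs of arrays had r under -0.3, and the direction of their values was kept because the labels state the dyes of every array. For 1 sample the title and the source name give different F2 numbers, and the title was used. The sample descriptions give a larger number of mice than the series design, and 311 arrays were used, the number in the design. Arrays carry no counts, and their number limits the precision.

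Probes were named from the probe-to-gene table of the platform, and symbols were brought up to date through a RefSeq gene table of the mouse assembly GRCm38.p6, used only for names and for the order of genes on chromosomes. Of 23388 probes 13645 named 1 gene, 48 several and 9695 none. Of the named, 12653 matched by Entrez ID, 4 by accession, 214 by symbol, 93 by an older symbol, and 681 kept the platform's name. Probes measured on at least 95% of arrays were kept (22863). Each of 11387 genes was read from the probe with fewest missing values, at a tie the first in order.

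The comparisons, the 32 gene lists, the 30 gene pairs, the thresholds and the rule for naming genes were set before the data were examined. Named genes are those of the measured pairs; the 25 with the largest SD; in each list up to 4 with the highest mean r with the rest, the lowest, and the 2 with the largest SD; the 12 with the largest margin for 1:2:1 and the 6 for 1:1; the Y-linked and X inactivation genes; and Apoe. Any other gene is said to have been chosen after its values were seen. Of 519 list genes 367 were measured.

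Spread was the SD over animals as a multiple of the median SD, with bootstrap 95% intervals over animals (1000 resamples), and genes at 3 or more times the median were counted. Lists with at least 4 measured genes were tested against 10000 random lists of the same size, two-sided for the median SD and one-sided for the mean pairwise Pearson r, with Benjamini-Hochberg adjustment over the lists at 0.05. Gene pairs had two-sided permutation tests of Pearson r and Spearman rho (100000 resamples), adjusted over the pairs, and r again without the 2 animals farthest from the median of the first gene. A gene or score counted as clustered when a mixture of 2 normals beat 1 normal and 1 Student t by a BIC of 10 with a minor weight of at least 0.1 and an Ashman D of at least 2. For clustered genes r was taken within each cluster of at least 6 animals. List scores were means of standardized values, with genes in both lists left out of both, and had permutation tests with 10000 resamples. Shapes were assigned when a 1:1, 3:1 or 1:2:1 mixture of normals with a common SD had the lowest BIC and beat the normal and the t by 10. Neighbours were compared after removing 10 principal components, 2 to 50 genes apart, with 1000 permutations of positions. Order along the F2 numbers was the lag-1 autocorrelation of 10 components, with 100000 permutations. Lags were counted in arrays sorted by F2 number, so gaps in the numbers were passed over. All work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, with the seed 2814.

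The methods were tested on simulated data. With clusters 3 SD apart, 99.8% of 1:1, 99.8% of 3:1 and 92.4% of 1:2:1 genes were called, and with 2 SD 9.6%, 19.4% and 3.4%. In 2000 normal and 2000 t distributed genes the calls were 0, but 69.55% of strongly skewed genes (gamma of shape 4) and 11.1% of mildly skewed ones (shape 16) were called as a mixture. Lists with a planted r of 0.2 were found in 10 of 10 cases and lists with none in 1 of 40. Lists with a planted spread were found in 20 of 20 cases and lists with none in 2 of 20. Bootstrap intervals held the true SD in 94.2% of cases.

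The alternatives tried were centring each array, probes on every array or on at least 0.5 of the arrays, animals with F2 numbers up to or above the median of 186, leaving out the 10 arrays of largest spread, the most variable probe per gene, and Spearman correlation. Others were the Y-linked log ratios as covariates, removal of 5 components, the median absolute deviation, a threshold of 2, a BIC margin of 20, other windows and component numbers for neighbours, trimmed values or the most variable genes for the pool slope, and a lag of 5. Chosen after the data were seen were subtraction of a running mean over 25 arrays in F2 order, skewed competitor distributions for the shapes, and leaving out arrays with a pancreas or muscle gene at 10-fold over the pool. Left out were 48 probes with several genes, unnamed probes, and the lists and pairs with too few measured genes. No groups of animals were compared.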

Results

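Liver RNA of 311 mice from an intercross of the inbred strains C57BL/6J and C3H/HeJ was measured, 1 array per animal. Both parental strains lacked a working Apoe gene, which codes for the apolipoprotein that clears remnant lipoproteins from blood. The animals were of both sexes and ate a high-fat, Western-type diet from 8 to 24 weeks of age. Each array set the RNA of 1 animal, labelled with Cy3, against a pool of equal portions of RNA from the study's samples, labelled with Cy5. All 311 arrays formed 1 group, because no sex, genotype or phenotype was used per animal, and the only label that differed between animals was the F2 number, from 2 to 359. The arrays held 23388 probes, of which 13645 named 1 gene. On a single array 1 to 2889 values were missing, with a median of 78. The animals were unreplicated, so the number of arrays limited the precision. Pearson r between 2 arrays over all probes ranged from -0.432 to 0.749, with a median of 0.159.

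Which liver transcripts differed most from animal to animal was asked first, since an intercross without labelled groups is described by its variation. Most transcripts varied little: over 11387 genes the median SD of the log10 ratio was 0.0667, which is 1.17-fold, and the median gene spanned 1.61-fold from its 5th to its 95th percentile. A small set varied far more, with 430 genes (3.78%) at 3 or more times the median SD. The largest SD belonged to Eif2s3y, a Y-linked translation factor subunit, at 13.5 times the median (95% interval 13.2 to 13.7, n = 311) and a span of 120-fold. The next were Sult2a2, a sulfotransferase, at 13.1 times and 201-fold, and A1bg, a plasma glycoprotein of female mouse liver, at 13.1 times and 262-fold. Their intervals (12.6 to 13.5 and 12.5 to 13.7) overlap that of Eif2s3y. With the most variable probe per gene Sult2a2 stood at 13.9 times and Eif2s3y at 13.0, so the first rank is not firm.

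Of the top 25 genes, 6 were in the fixed lists of female-biased and male-biased liver genes, A1bg among them. Hsd3b5, a steroid reductase of male liver, stood at 11.2 times the median SD (10.5 to 11.7), and Hao2, a peroxisomal oxidase of female liver, at 10.1 times (9.70 to 10.4). The male-biased fatty acid hydroxylases Cyp4a12a and Cyp4a12b stood at 10.1 and 7.85 times, and the male-biased cytochrome Cyp2d9 at 8.81 times. Kdm5d, a Y-linked histone demethylase, stood at 10.0 times and the solute carrier Slc22a26 at 10.1 times. Cidea, a lipid droplet protein that rises in fatty liver, spanned 104-fold at 10.3 times the median SD (9.61 to 11.0). Also in the top 25 were Serpina4-ps1, a serpin pseudogene, at 8.77 times, Sema3e, a semaphorin, at 8.51 times, and Camk2b, a calmodulin-dependent kinase subunit, at 8.00 times.

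The pancreatic trypsinogens Prss1, Prss2 and Try5 reached 8.53, 8.22 and 7.86 times the median SD. In animals with F2 numbers above the median alone, the multiples were 5.17 for Prss1 (SD of Prss1 as a multiple), 5.17 for Prss2 (SD of Prss2 as a multiple) and 4.87 for Try5 (SD of Try5 as a multiple). A further 8 genes of the top 25 had values at the limits of the scale, -2 and 2, without being clustered. They were Slc12a1, a kidney cotransporter, at 11.4 times with 22 such values, and Ppp1r9a, a neuronal scaffold protein, at 10.0 times with 16. Zdhhc11 followed at 9.37 times with 17 and Gprc6a, a receptor, at 8.54 times with 12. Dppa1 stood at 7.82 times with 13, the cadherin Cdh18 at 7.77 with 8, Sval2 at 7.72 with 12, and Atp6v1c2, a proton pump subunit, at 7.66 with 11. The value for Ppp1r9a was 0.820 times in animals with F2 numbers above the median and 0.890 times without the 10 arrays of largest spread (SD of Ppp1r9a as a multiple), where another probe of the gene was read. With the median absolute deviation, which discounts a few extreme arrays, the multiples of these 8 genes were 4.95 for Slc12a1, 4.12 for Ppp1r9a, 3.77 for Zdhhc11, 3.29 for Gprc6a, 2.55 for Dppa1, 3.78 for Cdh18, 2.74 for Sval2 and 3.41 for Atp6v1c2. The trypsinogens fell to 1.99 for Prss1, 2.51 for Prss2 and 2.44 for Try5 by that measure, Hsd3b5 to 7.70, Cidea to 7.98 and Camk2b to 6.2. Those that rose were Eif2s3y to 22.1, Hao2 to 16.8, Cyp4a12a to 17.0, Kdm5d to 15.9, Sult2a2 to 14.3, Slc22a26 to 14.1, Cyp2d9 to 13.4, Cyp4a12b to 13.4, Serpina4-ps1 to 12.1 and Sema3e to 10.4. Apoe itself stood at 1.72 times the median SD (1.56 to 1.89, n = 311), a span of 2.41-fold. Since both parental strains lacked a working Apoe gene, whether this probe read a transcript or background was not tested.

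**Figure D1:**
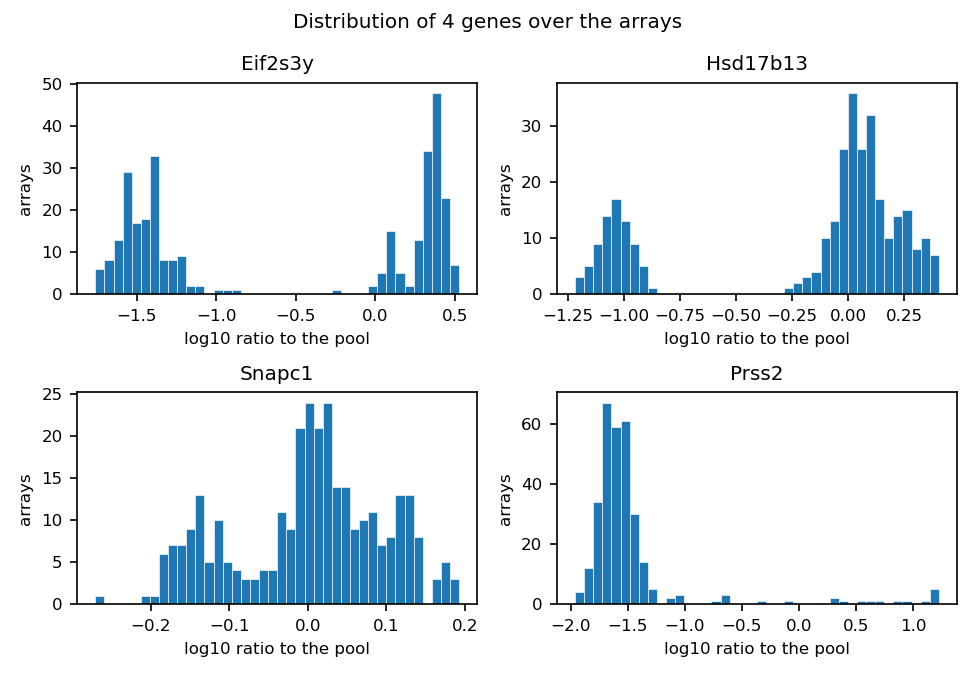
Histograms of the log10 ratio to the pool (x axis) over the arrays (y axis, number of arrays) for Eif2s3y, Hsd17b13, Snapc1 and Prss2. Eif2s3y split evenly, Hsd17b13 had 76 of 310 arrays in a separate low cluster, Snapc1 had a middle peak between a lower and a higher one, and Prss2 lay near its median of -1.59 on most arrays with a long tail to 1.23.

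Whether whole gene groups varied more than random groups was asked with 32 lists fixed in advance, of which 29 had at least 4 measured genes. At an adjusted p under 0.05, the median SD passed above that of random lists of the same size in 19 lists and below it in 0. The pancreas list (5 genes) had the largest median, 6.51 times that of all genes, followed by male-biased liver genes at 4.94 times (14 genes, 10 of them at 3 or more times) and female-biased liver genes at 4.69 times (15 genes, 12 of them). Fatty acid synthesis came next at 2.93 times, then gluconeogenesis and fasting at 2.49, cholangiocyte at 2.32 and lipid storage at 2.28. Cholesterol synthesis stood at 1.99 times. Endothelium (0.991), circadian clock (1.03), common reference genes (1.07), heat shock (1.11), the unfolded protein response (1.31), ribosomal proteins (0.845) and the respiratory chain (0.844) did not pass the test. The smallest adjusted p was 0.00058, from the smallest p the random lists can give, for 10 lists including acute phase, interferon response, macrophage and stellate cell and matrix. Random lists were not matched on expression level, which a ratio does not carry.

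Lipid synthesis genes moved together across animals. The 16 measured cholesterol synthesis genes had a mean pairwise r of 0.505, and 119 of their 120 pairs were positive. Lss, Mvd, Dhcr7 and Cyp51, all enzymes of the pathway, followed the rest of the list most closely (mean r 0.650, 0.631, 0.621 and 0.612), and Ebp, a sterol isomerase, least (0.271). Sqle, the squalene epoxidase, had the list's largest SD, 5.51 times the median of all genes and 14.4-fold in span. The 14 fatty acid synthesis genes had a mean r of 0.517. Fasn, the fatty acid synthase, spanned 6.92-fold, Acly, which makes cytosolic acetyl-CoA, 4.60-fold, and Pnpla3, a lipid droplet hydrolase, 8.16-fold. The desaturase Scd2 followed the list least (0.143). Lipid storage genes were less tightly joined (mean r 0.311, 7 genes): Pparg, the regulator of fat storage, led at 0.465, and Plin4, a lipid droplet coat protein, spanned 12.4-fold.

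Fatty acid oxidation genes had a mean r of 0.203 (17 genes), led by the thioesterase Acot1 (0.318) and the mitochondrial enzyme Hadhb (0.307), with the receptor Ppara lowest (0.0362). The list's spread, 1.39 times with adjusted p = 0.0473, lost its call when only probes on every array, the lower-numbered animals or the most variable probes were used (adjusted p 0.0544, 0.0708 and 0.0749 for spread of fatty acid oxidation). Bile acid and sterol export genes (15 genes) were weakly joined, with a mean r of 0.0642 (adjusted p = 0.00423). Their spread of 1.37 times did not pass (adjusted p = 0.0773). Abcg8, a sterol exporter, led that list (0.173), and Abcb4, the phospholipid exporter of bile, was lowest (-0.0801). Apolipoproteins and lipases (10 genes) spread more than random lists (1.69 times, adjusted p = 0.0129) but did not move together (mean r -0.0201, adjusted p = 0.816). In that list Apoa4, an intestinal and hepatic apolipoprotein, spanned 5.44-fold, Apob 4.52-fold, and Apoc2 had the lowest mean r (-0.135).

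Of 6 lists of inflammatory and immune cell genes, 5 moved together more than random lists. MHC class II genes, which present antigen, had a mean r of 0.548 (7 genes), led by H2-Aa (0.712), H2-DMb2 (0.660) and H2-DMb1 (0.619), and H2-Ea stood apart (0.212). Macrophage genes had a mean r of 0.423 (23 genes), led by the lysosomal proteases Lgmn (0.597) and Ctss (0.592). Marco, a scavenger receptor of Kupffer cells, spanned 23.1-fold, the widest of that list, and the Kupffer cell receptor Timd4 followed the list least (0.132). Interferon response genes had a mean r of 0.340 (24 genes), led by Ifit3 (0.522) and Gbp3 (0.493). Mx1, an antiviral GTPase, ran against its list (-0.260), and the chemokine Cxcl9 spanned 4.91-fold. Lymphocyte genes had a mean r of 0.291 (14 genes), led by the T cell genes Cd2 (0.481) and Cd3g (0.461), whereas Cd3e ran against them (-0.141). Acute phase genes, made by hepatocytes in inflammation, had a mean r of 0.414 (15 genes), led by Saa3 (0.530) and Orm2 (0.525). The iron hormone Hamp, the most variable of that list at 12.6-fold, was nearly unrelated to it (0.0421). The 4 plasma cell genes, of which Derl3 spanned 10.0-fold, did not pass either test (mean r 0.0538, adjusted p = 0.212; spread 1.95 times, adjusted p = 0.0679).

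Matrix, bile duct and cell cycle genes were joined as well. Stellate cell and matrix genes had a mean r of 0.322 (17 genes), led by the collagen crosslinker Lox (0.494) and the proteoglycan Lum (0.485), with Loxl1 opposed (-0.198). Mmp13, a collagenase, spanned 6.56-fold. Cholangiocyte genes had a mean r of 0.337 (7 genes, led by Epcam at 0.542), and Prom1, which was also in the female-biased list, followed them least (0.0343). Cholangiocyte scores rose with those of the pancreas list by r (0.335, permutation p = 1e-04, adjusted p = 0.000332, 0.20 without the 2 farthest) but not by rank (rho = 0.0579, p = 0.303). All 7 genes had positive weights on the fourth principal component, which held the pancreas genes, and coherence of cholangiocyte was 0.306 without the arrays of strong pancreas or muscle signal, a setting chosen after the data were seen. Proliferation genes had a mean r of 0.355 (18 genes), led by Birc5 (0.522) and Cdc20 (0.507), with Bub1 opposed (-0.252). Endothelial genes moved together (mean r 0.245, 10 genes, led by Eng at 0.396).

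Metabolic and stress lists were looser. Gluconeogenesis and fasting genes had a mean r of 0.180 and a spread of 2.49 times, with Pck1, the rate-limiting enzyme of glucose synthesis, first (0.325) and the cell cycle inhibitor Cdkn1a last (-0.0299). Xenobiotic metabolism genes had a mean r of 0.107 and a spread of 2.17 times, led by Cyp2c38 (0.260). Gsta2, a glutathione transferase, was the most variable gene there at 8.02-fold. The unfolded protein response had a mean r of 0.0994, led by the disulfide isomerase Pdia4 (0.266), the circadian clock list 0.0643, and heat shock 0.0631. In the clock list, Arntl, the positive limb of the oscillator, ran against the rest (-0.187), and its output Dbp led (0.179). Among housekeeping lists the mean r was 0.363 for the respiratory chain, 0.108 for ribosomal proteins and 0.0707 for common reference genes, where Hprt led (0.190). The last of these reversed with the most variable probe per gene (coherence of common reference genes, -0.00221). Adipose genes did not pass either test (mean r 0.0781, adjusted p = 0.140; spread 1.46 times, adjusted p = 0.288).

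In all, 26 of the 29 lists passed the one-sided test for a higher mean r than random lists of the same size. The smallest adjusted p, 0.000138 for 21 of them, is the smallest that the random lists can give. The genes of other tissues had the highest mean r, 0.840 for pancreas and 0.784 for skeletal muscle (8 genes). Without the 11 arrays on which a pancreas or muscle gene reached 10-fold over the pool, a setting chosen after the data were seen, spread of skeletal muscle was 1.27 times with adjusted p = 0.296. Its spread of 2.17 times in all animals, with adjusted p = 0.00193, rested on those arrays. The scores of the female-biased and male-biased lists fell into 2 clusters of animals. Within these the mean r of the female-biased list was 0.0657 in the 155 animals with lower scores and 0.153 in the 156 with higher scores. Within the clusters of the male-biased list it was 0.135 in the 155 lower and 0.404 in the 156 higher. The metallothionein, red cell, and X inactivation and Y-linked lists had 1, 3 and 2 measured genes and were not tested.

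**Figure D2:**
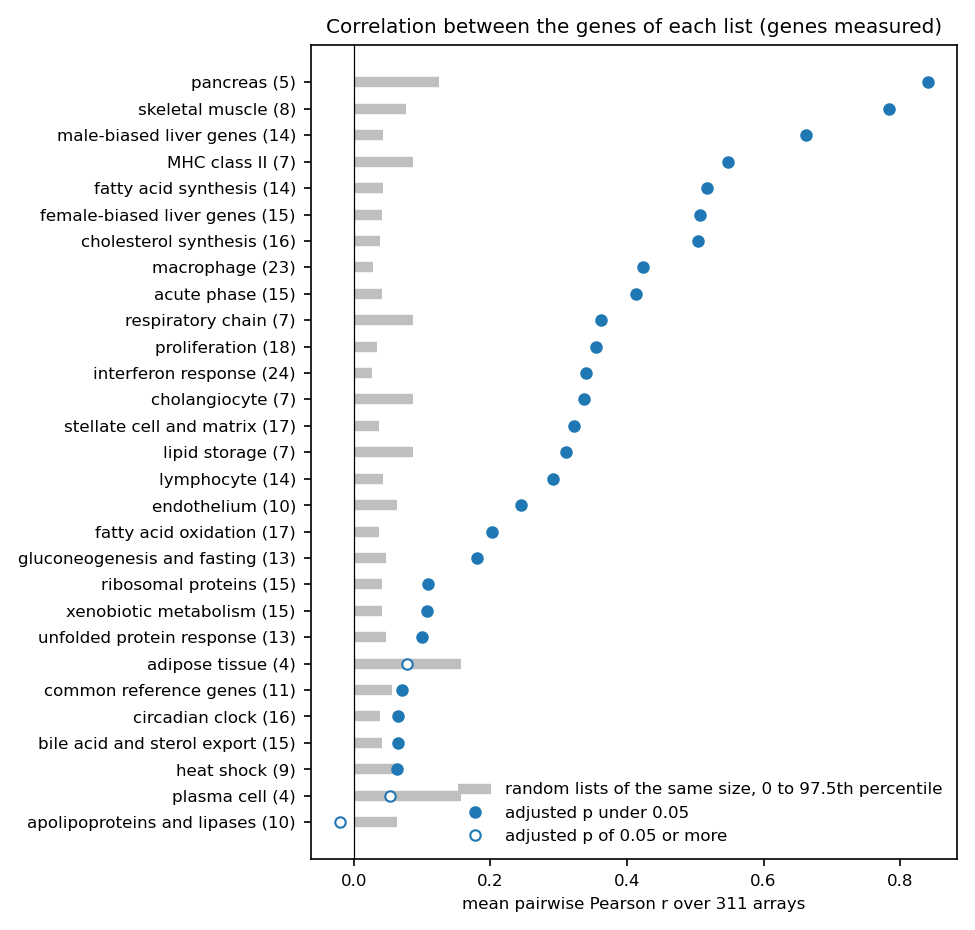
Mean pairwise Pearson r over the 311 arrays (x axis) of the measured genes of each list (y axis, number of genes in brackets), as points, with bars for random lists of the same size. Pancreas (0.840) and skeletal muscle (0.784) lay highest and apolipoproteins and lipases lowest (-0.0201), and the values of the male-biased and female-biased lists are pooled over 2 clusters of animals.

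How known partner genes moved together was measured for pairs fixed in advance, of which 14 of 30 had both genes measured. The tightest was Fasn with Acly (r = 0.861, 95% interval 0.832 to 0.887, rho = 0.862, n = 311). Sqle and Idi1, an isomerase of the same sterol pathway, followed (r = 0.812, 0.767 to 0.852, rho = 0.818). Abcg5 and Abcg8, the partner subunits of the sterol exporter, had r = 0.804 (0.760 to 0.842, rho = 0.779, n = 302). In the circadian clock, Per2 rose with Dbp (r = 0.646, rho = 0.612) and Arntl fell as Dbp rose (r = -0.637, rho = -0.534). The interferon genes Ifit1 and Irf7 had r = 0.665 (rho = 0.660, n = 306), and the gluconeogenic Pck1 and G6pc had r = 0.587 (rho = 0.567, n = 310). For these 7 pairs r without the 2 animals farthest from the median was 0.857 for Fasn, 0.812 for Sqle, 0.794 for Abcg5, 0.640 for Per2, -0.623 for Arntl, 0.645 for Ifit1 and 0.582 for Pck1. Their permutation p was 1e-05 for r and for rho, the smallest the permutations can give, with adjusted p of 1.71e-05 and 1.5e-05 over the 12 pairs without clusters.

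Weaker relations passed for Mki67 and Top2a, markers of dividing cells (r = 0.246, p = 5e-05, adjusted p = 7.5e-05; rho = 0.332, p = 1e-05; 0.279 without the 2 farthest). Cyp2b10 and Cyp3a11, both xenobiotic enzymes, had r = -0.167 (p = 0.0033, adjusted p = 0.0044; rho = -0.223, p = 8e-05; -0.217 without the 2 farthest). Pair Mki67 and Top2a had r = 0.129 (adjusted p = 0.147) in the higher-numbered animals and reversed to -0.106 with the most variable probes. Likewise pair Cyp2b10 and Cyp3a11 had r = -0.0925 (adjusted p = 0.122) with the Y-linked log ratios as covariates and reversed to 0.0254 with 5 principal components removed. Cpt1a and Pdk4, which control the entry of fuel into mitochondria, did not pass (r = 0.0955, p = 0.0918, adjusted p = 0.110; rho = 0.115, p = 0.0417; 0.0940 without the 2 farthest). Nor did the bile acid genes Cyp8b1 and Abcb11 (r = -0.0740, p = 0.193, adjusted p = 0.211; rho = -0.106, p = 0.0620; -0.0885 without the 2 farthest), although pair Cyp8b1 and Abcb11 had r = 0.188 (adjusted p = 0.0011) with the Y-linked covariates. Cd68 of macrophages and Col1a1, a fibrillar collagen, had r = -0.0227 (p = 0.692, adjusted p = 0.692; rho = -0.0450, p = 0.431; -0.0357 without the 2 farthest), but pair Cd68 and Col1a1 had r = 0.372 with the most variable probes.

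In both remaining pairs 1 gene was clustered, so r was taken within its clusters. The 3:1 mixtures of these genes, Scd1 and Saa1, did not also beat the skewed distributions described below. Their smaller clusters may thus be the tail of 1 skewed distribution, and a cut on the gene narrows the range over which r is taken. Fasn and the desaturase Scd1 had r = 0.405 in the 37 animals of the lower Scd1 cluster (permutation p = 0.0126, rho = 0.398, p = 0.0152, 0.307 without the 2 farthest). In the 270 of the higher cluster r was 0.665 (p = 1e-05, rho = 0.670, p = 1e-05, 0.662 without the 2 farthest). Saa1 and Lcn2, both acute phase genes, had r = 0.589 in the 266 animals of the lower Saa1 cluster (p = 1e-05, rho = 0.580, p = 1e-05, 0.578 without the 2 farthest). In the 45 of the higher cluster r was 0.384 (p = 0.00871, rho = 0.475, p = 0.00097, 0.408 without the 2 farthest). The largest adjusted p over these 4 values was 0.0126 for r and 0.0152 for rho.

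Which gene groups rose and fell together was measured with 1 score per list and animal for the 26 coherent lists. Immune groups formed a block in which every pair of MHC class II, macrophage, interferon response and lymphocyte scores had r of 0.558 or more. These r were pooled over both clusters into which the first principal component split the animals. Genes of these lists had median correlations with that component of -0.241, -0.445, -0.425 and -0.255, in that order. A difference shared between the clusters can raise each r. With the Y-linked log ratios as covariates these pairs kept their sign and call. MHC class II and macrophage scores had the highest r of all (0.728, 0.670 to 0.780, rho = 0.730). Cholesterol and fatty acid synthesis scores rose together (r = 0.719, 0.640 to 0.787, rho = 0.738). Stellate cell and matrix scores rose with those of lipid storage (r = 0.591, rho = 0.584), proliferation (r = 0.521, rho = 0.527) and common reference genes (r = 0.510, rho = 0.474). Bile acid and sterol export scores fell as lipid storage (r = -0.575, rho = -0.586) and matrix scores (r = -0.538, rho = -0.510) rose.

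Of 325 pairs of lists, 276 had scores without clusters, and 151 passed at an adjusted p under 0.05 (75 positive, 76 negative). In 12 of them r was at least 0.5 in size, 10 positive and 2 negative. For the 12, permutation p was 1e-04 for r and rho, the smallest possible, with an adjusted p of 0.000332. Without the 2 farthest animals r was 0.721 for MHC class II and macrophage, 0.724 for both lipid syntheses, 0.578 for lipid storage and matrix, and from 0.495 to 0.632 for the other positive pairs. It was -0.551 for bile acid export with lipid storage and -0.520 with matrix. The other pairs of immune scores had r of 0.647 for interferon response and macrophage (rho = 0.625), 0.617 for interferon response and lymphocyte (rho = 0.617), 0.610 for MHC class II and lymphocyte (rho = 0.634), 0.602 for interferon response and MHC class II (rho = 0.591), and 0.558 for macrophage and lymphocyte (rho = 0.573). Because 3 principal components varied along the F2 numbers, the lower-numbered and higher-numbered animals were also taken apart. This split leaves runs of neighbouring animals in place, and the permutation tests took the animals as exchangeable. Scores MHC class II and macrophage had r = 0.707 and 0.753, scores cholesterol synthesis and fatty acid synthesis 0.665 and 0.767, and scores lipid storage and stellate cell and matrix 0.630 and 0.581. With the first 5 principal components removed the last of these reversed to -0.149, as did scores bile acid and sterol export and stellate cell and matrix to 0.201 and scores stellate cell and matrix and proliferation to -0.0346. With these components removed r was 0.118 (adjusted p = 0.0742) for scores stellate cell and matrix and common reference genes and -0.0763 (adjusted p = 0.273) for scores bile acid and sterol export and lipid storage.

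**Figure D3:**
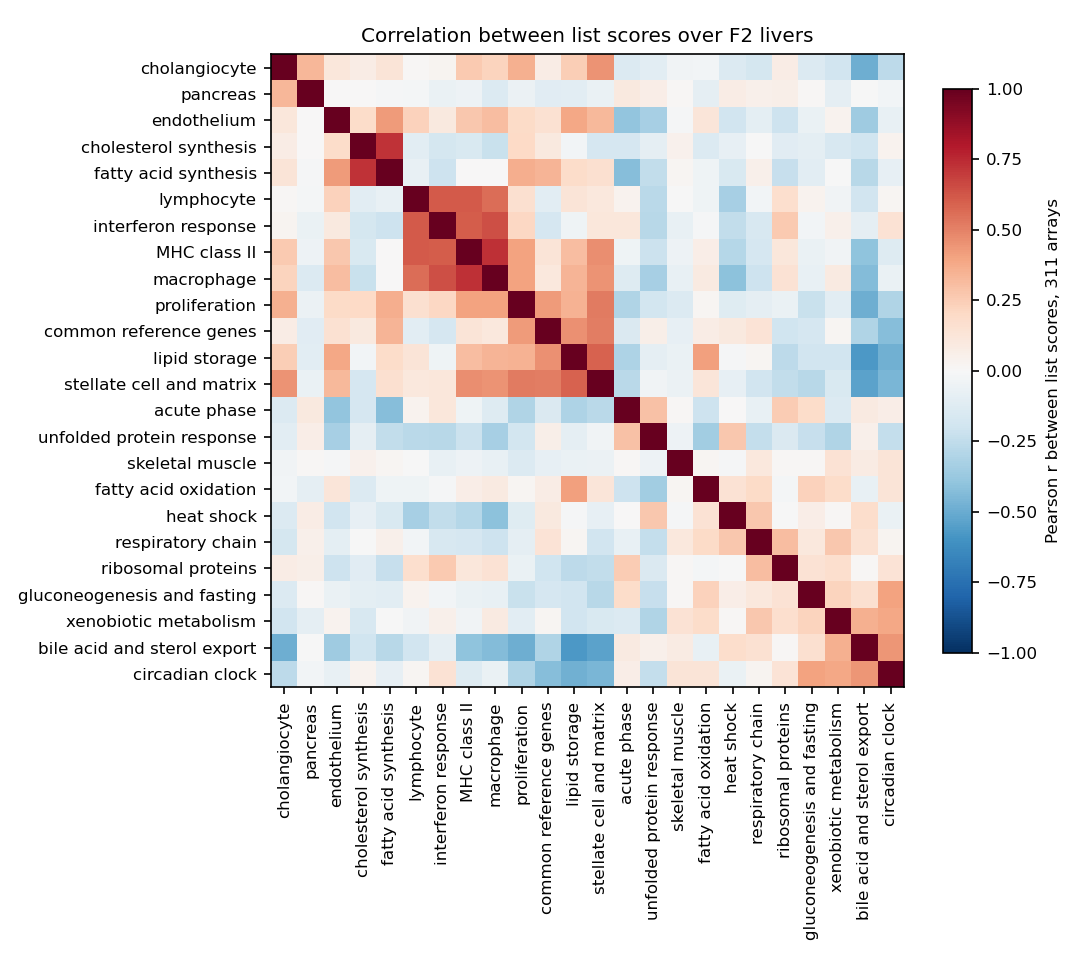
Pearson r over the 311 arrays between the scores of the 24 lists whose scores were not clustered (both axes, lists; color, r from -1 to 1). MHC class II, macrophage, interferon response and lymphocyte formed a positive block (0.558 to 0.728), and bile acid and sterol export opposed lipid storage (-0.575) and stellate cell and matrix (-0.538).

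At a locus of an intercross, offspring carry parental alleles in the ratio 1:2:1, a recessive or dominant effect gives 3:1, and the sexes give about 1:1, so the shape of each gene's distribution was compared with these. Of 11387 genes, 458 had a mixture shape: 84 were 1:1, 357 were 3:1 and 17 were 1:2:1. The 1:1 genes with the largest margins were the Y-linked Eif2s3y and Kdm5d, whose cluster means lay 58.9-fold and 20.0-fold apart. Where the low cluster lacks the transcript, its level is probe background, so these gaps, and the SD and span of Eif2s3y and Kdm5d, do not measure a fold change, and intensities over background were not used here. Next by margin were Cyp4a12b (9.84-fold), Cyp4a12a (18.6-fold), Slc22a26 (19.0-fold) and Cyp2d9 (12.9-fold). Of the 29 measured genes of the female-biased and male-biased lists 16 were 1:1 and 5 were 3:1.

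For the 17 genes called 1:2:1, a fit of 3 levels held at even spacing gave a median step of 1.47-fold. Snapc1, a subunit of the snRNA activating complex, had the largest margin and a step of 1.34-fold. Next were Ngdn (1.47-fold), Mcur1, a regulator of the mitochondrial calcium uniporter (1.57-fold), and Aqp11, an aquaporin (1.60-fold). The other genes of the first 12 were Ngrn (1.24-fold), PIGX (1.43-fold), the mitochondrial ribosomal Mrps12 (1.33-fold), the integrin Itga9 (1.51-fold), Rims1 (1.43-fold), the transcription factor Usf1 (1.38-fold), the flippase Atp10d (1.66-fold) and the death ligand Tnfsf10 (1.57-fold). Of the 17, only Itga9 did not also beat the skewed distributions described below.

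Among the 3:1 genes the minor cluster was low in 147 and high in 210, held a median of 21.8% of animals, and lay a median of 1.83-fold away. Chosen after their values were seen, Hsd17b13, a lipid droplet enzyme, had 76 of 310 animals 13.5-fold lower, Xdh, the xanthine dehydrogenase, 78 of 311 animals 7.21-fold lower, and Ifi202b, an interferon-inducible gene, 68 of 310 animals 10.8-fold lower. Cidea was also called 3:1, with its minor cluster of 80 animals 25.0-fold higher. A single skewed distribution can be called 3:1 by this rule: when skewed distributions also had to be beaten, 90 of the 3:1, 73 of the 1:1 and 16 of the 1:2:1 genes passed (179 in all for distribution shape). Of those 90, the minor cluster was low in 62 and high in 28, the opposite balance to all 3:1 genes. With the Y-linked log ratios as covariates distribution shape fell to 234 genes: number of 1:1 genes was 6, number of 3:1 genes 211 and number of 1:2:1 genes 17.

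Neighbouring genes shared more of their variation than genes on different chromosomes. Over 10763 genes, pairs 2 to 50 measured genes apart had a mean squared r of 0.0137, against 0.0104 for pairs on different chromosomes, a ratio of 1.32. Adjacent genes reached 0.0223, and the value fell with distance to 0.0110 at 201 to 400 genes apart. In 1000 permutations of the gene positions the highest excess was 0.00015, against 0.00331 observed (one-sided p = 0.001, the smallest they can give). The squared r is across animals but averaged over gene pairs, which are not independent replicates. Leaving out pairs of like-named genes, a way to omit families, gave an excess of 0.00323 (chromosome neighbours).

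**Figure D4:**
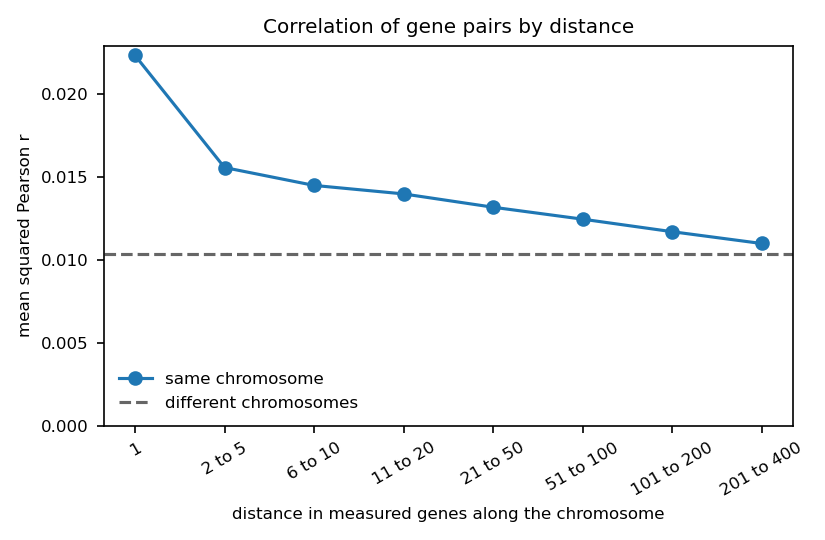
Mean squared Pearson r of gene pairs (y axis) by their distance along the chromosome in measured genes (x axis), with 10 principal components removed. Pairs on 1 chromosome fell from 0.0223 to 0.0110 and lay above the dashed line for pairs on different chromosomes (0.0104) at every distance.

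Along the F2 numbers, animals with neighbouring numbers resembled each other in 3 of the first 10 principal components. The first component (14.7% of the variance) split the animals into 2 clusters, and its 25 genes of largest weight included both Y-linked genes, 5 female-biased genes and 4 male-biased genes. It had a lag-1 autocorrelation of 0.621 (permutation p = 1e-05, the smallest possible, adjusted p = 5e-05). At a lag of 5 arrays in that order the value was -0.0545. The third component (5.32%) had 0.368 (p = 1e-05, adjusted p = 5e-05) and 0.240 at a lag of 5, and none of its 25 leading genes was in a fixed list. The seventh (2.28%) had 0.145 (p = 0.0093, adjusted p = 0.0310), with 1 fatty acid synthesis gene among its 25. The second component (7.34%) had 4 matrix genes among its 25 and the fourth (3.13%) all 5 pancreas genes, and neither passed at lag 1 (adjusted p = 0.270 for both), but at a lag of 5 they had -0.166 and 0.203 (adjusted p = 0.0104 and 0.0075 for lag-1 of component 2 and lag-1 of component 4 at that lag).

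The reference was a pool of all samples, so a gene's mean ratio to it ties the direction and base of the values. Of the 430 genes at 3 or more times the median SD, 302 had a mean log10 ratio below 0. A1bg stood at -0.861 and Eif2s3y at -0.570, whereas the 8 unclustered genes of the top 25 with values at the limits lay above 0, from Atp6v1c2 at 0.0384 to Gprc6a at 0.108. Across genes the slope of the mean on the variance was -1.04 (-1.27 to -0.834), close to the -1.15 of log10 ratios of sample over pool and beyond the -0.5 of natural and -0.347 of log2 ratios. The correlation behind it (r = -0.584) is across genes, which are not independent replicates. A second check, the median of the genes' mean linear ratios to the pool, should lie near 1. For sample over pool it was 1.04 with log10, 0.997 with natural and 0.995 with log2 ratios, so it did not single out log10. With log10 of pool over sample it was 1.21.

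Probes of 1 gene gave the only repeated measurement. In 1281 genes with more than 1 probe, 4601 probe pairs had a median r of 0.165 (interval over genes 0.109 to 0.233), with quartiles of -0.00343 and 0.647, against a median of -0.00341 for probes of different genes. Genes with many probes, up to 35, weigh more in that median, and the median over genes of each gene's median r was 0.0878. In the 97 pairs where both probes had 2 or more times the median SD the median r was 0.215. In 2884 pairs with the smaller SD under the median it was 0.104. Values of single genes rest on 1 probe each and share this limit. With probes measured on every array, same-gene probes had a median r of 0.252.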

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

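All alternatives were chosen before the data were examined except 3: the skewed distributions, the running mean over F2 numbers, and leaving out arrays with strong pancreas or muscle signal. Over the summary results, 83 of 96 alternatives left the value within its spread, or a count within 1.5 times, 13 moved it and 0 reversed it. For the chromosome neighbours excess, a value counted as unmoved when its sign and its call held, whatever its size. Among single results, 242 of 256 values for list spread, 336 of 343 for list coherence, 128 of 139 for gene pairs, 139 of 144 for list scores and 155 of 213 SD multiples of the top 25 genes stayed. The other 58 SD multiples moved and 0 reversed, with 24 of the moves under the median absolute deviation, which weighs tails less by construction. For Ppp1r9a, the SD of Ppp1r9a as a multiple fell to 0.820 above the median F2 number and 0.890 without the 10 arrays of largest spread, as another probe then had the fewest missing values. The number of coherent lists ranged from 21 to 27, and the chromosome neighbours excess from 0.00161 to 0.00534.

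With probes measured on every array fewer genes and pairs were tested, which by construction lowers the counts: spread between mice gave 224 genes of 6560 (203 shared), fixed gene pairs 4 of 7, and distribution shape 287 genes. There the slope of the pool relation was -1.32 and the median r of same-gene probes 0.252; the cause was not tested. With fewer animals, those with F2 numbers up to the median and above it, distribution shape gave 305 and 273 genes. In the latter the pool relation was -0.831; the cause was not tested. There, too, spread of skeletal muscle reversed to 0.967, and with the median absolute deviation, which discounts a few extreme arrays by construction, to 0.993. With the most variable probe per gene, coherence of common reference genes turned to -0.00221, pair Mki67 and Top2a to -0.106 and pair Cd68 and Col1a1 to 0.372; the cause was not tested. With Y-linked log ratios as covariates distribution shape gave 234 genes (190 shared): number of 1:1 genes fell from 84 to 6, as the covariates remove differences tied to them, and number of 3:1 genes from 357 to 211 (166 shared), for which the cause was not tested. There pair Cyp8b1 and Abcb11 turned to 0.188; the cause was not tested. Removing 5 components takes out shared variation by construction: list scores gave 3 pairs, pair Cyp2b10 and Cyp3a11 turned to 0.0254, pair Cyp8b1 and Abcb11 to 0.158, scores lipid storage and stellate cell and matrix to -0.149, scores stellate cell and matrix and proliferation to -0.0346, and scores bile acid and sterol export and stellate cell and matrix to 0.201. A threshold of 2 gave spread between mice of 1253 genes, and a BIC margin of 20 gave distribution shape of 263, both by construction, as did the skewed distributions with 179. At a lag of 5 lag-1 of component 1 became -0.0545 and lag-1 of component 2 became -0.166; the cause was not tested. Without signal intensities over background, the share of spread due to weak probes was not analysed here.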

Other observations

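The test of linkage in the 3:1 genes that also beat skewed distributions, the counts of shared animals in linked gene pairs, and all genes named here outside the fixed lists were chosen after the results were seen; the other tests were set before theirs.

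Some neighbouring 3:1 genes that also beat the skewed distributions split the same animals. Of 27 pairs of such genes lying 2 to 50 measured genes apart, 7 shared at least 3 times the animals in their minor clusters that independence gives. H2-Ea, an MHC class II chain, and H2-Q5, an MHC class I gene, both on chromosome 17, were low together in 70 animals, where 18.0 would be shared by chance. Gfer and Decr2 on chromosome 17 shared 77 animals (20.4 by chance), Trim34a and Trim30d on chromosome 7 shared 70 (18.3 by chance), and Abhd1 and Poln on chromosome 5 shared 77 (21.4 by chance). In 11 other pairs the minor clusters shared at most 1 animal, where independence gives 17.2 to 22.2. Their squared r ran from 0.306 (Pianp with A2ml1) to 0.716 (Cebpe with Supt16). The genes of these pairs were thus also related across animals, although different animals made up their minor clusters. Hsd17b13 and Dgkq on chromosome 5 shared 0 (17.2 by chance), as did Abhd1 and Rbks (20.3 by chance), and C4b, a complement gene, shared 0 with H2-Ea (17.3 by chance). The pairs are not independent, since genes such as H2-Ea and Abhd1 are in more than 1. The remaining 9 pairs had a squared r of 0.0824 or less and included Pdia3 with Bmf on chromosome 2, which shared 31 animals (26.1 by chance).

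The Y-linked genes Eif2s3y and Kdm5d were both high in 155 animals and both low in 156, with 0 animals differing. In Eif2s3y an empty interval of 0.656 on the log10 scale parted the animals, from -0.875 to -0.219. The widest empty interval of Kdm5d, from -0.541 to -0.256, had 155 arrays below it. Its lower mixture cluster held 156, so the full match depends on the cut of the mixture. The female-biased score was in its lower cluster in all 155 animals with high Eif2s3y and in its higher cluster in all 156 with low Eif2s3y. The male-biased score ran the other way with few exceptions: of animals with high Eif2s3y 154 had a high score and 1 a low score, and of animals with low Eif2s3y 154 had a low score and 2 a high score. Among the 25 genes of largest weight in the first component, Alas2, the erythroid heme enzyme on the X chromosome, was 1:1 with a gap of 2.77-fold, and Abcg2, an exporter, was 1:1 with a gap of 2.58-fold. These genes were read as values, and no animal was assigned a sex.

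Genes with a 3:1 shape were weighed against technical causes. A few aberrant arrays could not be judged by the bound set beforehand. A minor cluster held a median of 21.8% of animals, so 10 arrays could not hold that large a share of memberships. Of minor-cluster memberships, the 10 arrays of largest spread held 4.18% and the 10 with the most 7.23%, where an even share is 3.22%. However, 1 array was in the minor cluster of 54.6% of the genes (median 18.8%). A single skewed distribution stays open for most, since 25.2% (90 of 357) also beat a skew-normal and a shifted gamma distribution. Parental alleles segregating in the cross may account for part. The median squared r of near pairs exceeded that of pairs on different chromosomes by 0.00433 (highest permuted 0.00181, permutation p = 0.001, the smallest possible). Over all genes near pairs also had an excess, of 0.00331 in mean squared r. Genes without the 3:1 shape were not tested alone, so the 0.00433 does not set the 3:1 genes apart. In the genes past the skewed distributions the excess of the median was 0.506 (medians 0.509 and 0.00255, 27 near pairs). A strain variant under 1 probe, which would also follow linkage, cannot be told apart from a change in transcript level: the median r with the 61 other probes of 38 such genes was 0.237, with 22 above 0.5 and 28 at 0.2 or less. For the remaining genes with more than 1 probe that median was 0.117.

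The order of the first component along the F2 numbers was weighed next. Array quality drifting along the numbering was argued against, since the larger rank correlation with array spread or missing values was 0.0822 in size. Runs of animals of 1 sex in the numbering may account for most of it: Eif2s3y and Kdm5d themselves had lag-1 values of 0.598 and 0.581. With the Y-linked log ratios as covariates, which left 8.09% of the component's variance, its lag-1 value fell from 0.621 to 0.156 (permutation p = 0.00581). Because so little of the component was left, this fall alone decides little. The autocorrelation that remains was not explained, and litter and array run, for which no labels were used here, stay open.

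Pancreas and muscle transcripts, from lists fixed in advance, were weighed last. All 13 measured genes had a skewness of 1 or more (3.06 to 5.48), against 9.34% of all genes, and Prss2, Cel and Pnliprp1 reached 16.8-fold, 17.8-fold and 19.9-fold over the pool, with 6 arrays each at 10-fold or more, and Tnnc2 and Atp2a1 19.1-fold and 19.3-fold, with 4 each. These values are consistent with tissue carried over with a few livers. A share of RNA that differed for all other-tissue lists alike stays open: pancreas and muscle scores had r = 0.0117 (p = 0.840) but rho = 0.477 (p = 1e-04, the smallest possible), and the bound set beforehand on r took no account of their skew. Expression within the liver was not tested and stays open.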
